A study of Homo sapiens with 4 samples.

How the data were processed

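Human CD4+ T cells, the helper T cells of the immune system, were isolated by negative selection from a lymphocyte fraction, per the labels' protocols, and were either left resting or activated for 18 hours with beads that carry antibodies against CD3 and CD28, at 1 bead per cell. Total RNA of each of the 4 samples was hybridised to 1 one-colour oligonucleotide array of 54675 probe sets. The labels name the samples M and T in each group without saying what the letters stand for, and the samples are called resting M, resting T, activated M and activated T here. They do not say whether the samples of a group came from separate donors or cultures, so the p-values measure only the spread between these samples, which may be technical.

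The deposited values are probe set intensity values on a linear scale, MAS5 signals that were made with GCOS 1.40 and MAS5 per the submitters' processing notes. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a common mean. The 2% trimmed mean of the deposited signal was 1000 in every array, computed from the values. The scaling target, detection calls, scan dates and any batch are not given in the sources used here, so signal over background could not be set per probe set and no batch could be tested. The number of arrays limits the precision.

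Signals were transformed to log2(signal + 50.5), where the pseudocount of 50.5 is the mean over the arrays of their 25th percentiles of signal. It keeps values near background from dominating a log scale, and it understates the fold change of dim genes. A probe set was tested where at least 2 of the 4 arrays, of whichever group, were at or above their own array's median. The 62 control probe sets were left out of the tests, and 28970 probe sets were tested while 25643 were too dim. Gene names came from the platform's annotation table, in which 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none. The Entrez IDs of 41037 of the 1-symbol probe sets matched the gene table of assembly GRCh38.p14, which was used for names only, 54 did not match, and 0 symbols changed. A gene was represented by the 1-symbol probe set with the highest mean log2 value, and by a probe set prone to cross-hybridisation (ID ending in _x_at) only where it had no other, which gave 12414 tested genes. XIST, Y-linked genes, HLA genes and immunoglobulin or T-cell receptor segments are not named.

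Activated cells were compared with resting cells in limma 3.58.1 under R 4.3.3, with a linear model per probe set, moderated variances with a trend on mean signal and no block. Tests were two-sided with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. With 2 samples per group an exact permutation test cannot go below 0.33, which is why a model that shares variance across probe sets was used. All adjusted p-values of genes come from this limma fit, fold changes are on the scale of log2(signal + 50.5), and errors of log2 fold changes are standard errors.

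Before the data were examined, 26 gene lists and 8 lists of markers of other cell types were fixed, with 807 genes in all, of which 695 were tested and 70 were not annotated to exactly 1 gene symbol in the table used here. Each list was set against all other tested genes with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists that had at least 3 tested genes. camera with a correlation estimated per list and the self-contained test fry were run beside it. Counts of changed members are also given with p-values adjusted over the list alone.

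Genes were named by a rule fixed at the same time. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose activated arrays both lay on one side of both resting arrays, up to 4 members past the threshold with the largest absolute change in each list, the 2 members with the smallest p where none passed, and CD4 and CD3E as background. Other genes that are named, as the members behind a small count or as a single feature of a list, were chosen after their values were seen. Alternatives covered the pseudocount (none, the mean of the arrays' medians, or a floor), the scaling of the arrays (quantile normalization, or centring on medians), the filter (none, or the 75th percentile), the variance trend, the letter as a block, the mean of a gene's probe sets, a fold threshold of 2 and leaving out each array in turn.

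The fit was tested on simulated data with known changes, 28923 probe sets of which passed the filter. It recovered 3 of 65 probe sets changed by 1 on the log2 scale (4.62%), 16 of 64 changed by 2 (25%) and 54 of 66 changed by 4 (81.8%), and 5 unchanged probe sets were called, 6.41% of all calls. The other 28728 tested probe sets were unchanged in the simulation, whereas 5874 of 28970 passed the threshold in the data. Benjamini-Hochberg adjustment depends on the share that changes, so these recovery rates do not carry over to the data. The simulated noise was normal, with variances drawn from the fitted model itself. The share of false calls therefore did not test departures of the real arrays from that model. Of simulated lists of 25 genes, camera with the preset correlation called 4 of 4 that were shifted by 1 and 0 of 26 that were not. The simulated genes varied independently, so this did not test false calls of lists whose members vary together. In the data the estimated correlation ranged from -0.208 for the B cell markers to 0.852 for the monocyte markers. With an estimated correlation camera called 0 of 4 shifted simulated lists, so in this design it made no call even where a shift was present. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.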

Results

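The series concerns how nucleosome positions in human CD4+ T cells change with activation, and the arrays analysed here record gene expression in the same 2 states. Resting cells and cells activated for 18 hours were each represented by 2 arrays. Median MAS5 signals were 214.1 in resting M, 221.7 in resting T, 147.2 in activated M and 203.7 in activated T. The 3' to 5' signal ratio, a sign of RNA quality, was 1.325 and 1.126 for GAPDH in resting M and T and 1.072 and 1.208 in activated M and T. For beta-actin it was 1.413 and 1.364 in the resting arrays and 1.134 and 1.269 in the activated arrays. Log2 values correlated across probe sets, which are not independent replicates, at r = 0.908 between the resting arrays, 0.939 between the activated arrays and 0.784 to 0.816 across the groups.

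To characterize the response to activation, gene expression in activated cells was compared with that in resting cells. Effector cytokine genes were among the largest rises. IL2, the T-cell growth factor, rose 408-fold (log2 8.67 ± 0.57, SE, limma adjusted p = 4.97e-06), from a signal of 105.5 ± 139 to 50664 ± 16079 (SD, n = 2 per group). IL3 rose 207-fold, IFNG, the gene of interferon gamma, rose 100-fold (log2 6.64 ± 0.46) from 751.7 ± 535.9 to 74142 ± 31641 (SD), and LTA and TNF rose 54.5-fold and 34.4-fold. KLF2, a transcription factor of quiescent T cells, had the largest fall, 82.4-fold (log2 -6.36 ± 0.37, limma adjusted p = 2.32e-06), from 58302 ± 28637 to 613.6 ± 18.93 (SD).

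The other genes among the 12 largest rises were ZBED2 (328-fold), the costimulatory receptor gene TNFRSF9 (51.9-fold), EPOP (45.2-fold), the chemokine genes CXCL9 (44.4-fold) and CCL4 (35.7-fold), PSAT1, an enzyme of serine synthesis (35.7-fold), and BYSL, a ribosome assembly factor (32.8-fold). The log2 standard errors of these 7 genes ranged from 0.43 to 0.78. The folds and ranks of genes with low resting signals depended on the pseudocount: without one and with a larger one the log2 fold change was 10.33 and 7.44 for IL2, 9.63 and 6.96 for ZBED2, and 10.68 and 5.89 for IL3, whose resting signals were 8.833 and 5.932. CXCL9 differed between the activated arrays, with signals of 1291 in M and 12502 in T. The other genes among the 12 largest falls were the inducible heat-shock gene HSPA6 (61.5-fold), TSC22D3, a glucocorticoid-induced gene (61.0-fold), PIK3IP1, an inhibitor of phosphoinositide 3-kinase (50.6-fold), the aquaporin gene AQP3 (50.1-fold), ADA2, an adenosine deaminase (47.1-fold), and IRS2, an insulin receptor substrate (43.1-fold). RASGRP2 (41.4-fold), MYADM (39.3-fold), PDCD4 (36.7-fold), TMEM71 (34.5-fold) and the AP-1 subunit gene FOSB (32.5-fold) completed them. Falls to low activated signals depended on the pseudocount too. Without one and with the larger one the log2 fold change was -6.03 and -4.14 for PDCD4, -5.8 and -4.26 for TMEM71, and -6.34 and -5.3 for HSPA6. With the larger one HSPA6 fell less than TSC22D3 (-5.78) and PIK3IP1 (-5.4).

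**Figure D1:**
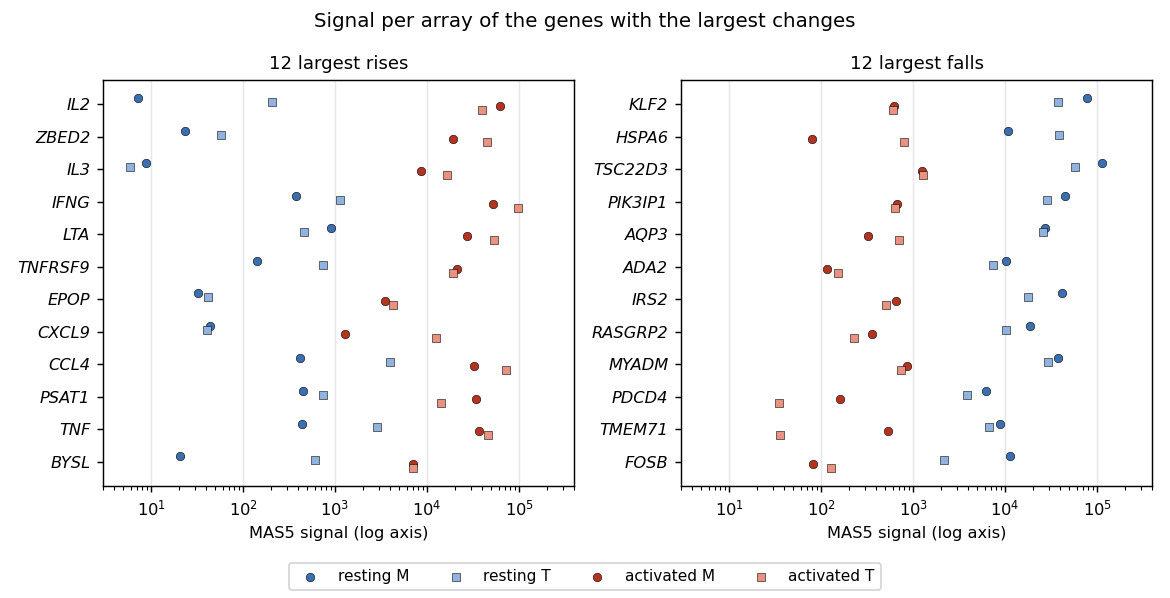
Signal of the 12 genes with the largest rises (left) and the 12 with the largest falls (right) in each of the 4 arrays, 1 point per array, on a log axis of MAS5 signal. Circles stand for M and squares for T, blue for resting and red for activated; for IL2 the resting arrays lie at 7.201 and 203.8 and the activated arrays at 62034 and 39295.

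Of 12414 tested genes, 1558 (12.6%) were higher and 1376 (11.1%) were lower in activated cells at a limma adjusted p under 0.05, and 1481 and 1329 of them changed at least 2-fold. Of 28970 tested probe sets, 2571 (8.87%) were higher and 3303 (11.4%) were lower. The direction of the calls depended on the scaling of the arrays. With the deposited scaling 53.1% of the called genes and 43.8% of the called probe sets were higher, against 68.6% and 60.9% with each array centred on its median and 58.1% and 51.6% with quantile normalization. These scalings moved the median log2 fold change of all tested genes by 0.25 and 0.14. The median absolute log2 difference was 0.475 between the resting arrays, 0.398 between the activated arrays and 0.674 between the group means. Without activated M 1134 genes passed the threshold and without activated T 1535, against 2934 with all arrays. Where a list's count of at least 4 changed genes moved by over 1.5 times, its range over the unpaired alternatives, those that left out an array included, is given beside it.

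Cytokine and chemokine genes rose as a group. Of 27 tested, 23 rose, 2 fell and 2 did not pass the threshold, with a median log2 fold change of 3.99 (limma camera adjusted p = 6.54e-13, and adjusted p = 0.344 with an estimated correlation). Adjusted over the list alone, 23 rose and 2 fell. Genes of several helper lineages were among those that rose, including IL17A (log2 4.43 ± 0.52), IL4 (4.17 ± 0.60), IL5 (3.99 ± 0.56) and IL21 (3.03 ± 0.53). CCL5 (-2.20 ± 0.31) and TGFB1 (-1.65 ± 0.34) were the 2 that fell, and CXCL8 (0.42 ± 1.36) and IL6 (1.57 ± 0.75) did not pass.

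Activation receptors and costimulatory molecules rose in 12 of 23 tested genes, with 0 falls and a median log2 fold change of 1.27 (limma camera adjusted p = 7.3e-07, and adjusted p = 0.338 with an estimated correlation), or 13 rises and 0 falls adjusted over the list alone. IL2RA, the alpha chain of the interleukin-2 receptor, rose 29.5-fold (log2 4.88 ± 0.33), from 745.5 ± 155.9 to 23226 ± 1591 (SD, n = 2 per group, limma adjusted p = 5.56e-06). TNFRSF18 rose 14.4-fold and CD200 13.8-fold. CD69, an early activation marker, differed by a log2 fold change of 0.09 ± 0.59 (limma adjusted p = 0.939), with resting signals of 52234 in M and 9344 in T.

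Transcription factors of the activation response went both ways, with 11 of 29 tested genes higher (7 to 11 over the alternatives), 9 lower (5 to 10) and 9 not past the threshold. Adjusted over the list alone, 11 were higher and 11 were lower. ZBED2, the AP-1 gene FOSL1 (23.4-fold, log2 4.55 ± 0.49), IRF4 (log2 4.52 ± 0.30) and MYC (2.98 ± 0.27) rose. JUN fell 27.9-fold (log2 -4.80 ± 0.48), as did FOSB, FOS (-4.26 ± 0.80) and JUND (-2.00 ± 0.25). The list's median log2 fold change was -0.46 while its mean was 0.20 and camera's direction was up (limma camera adjusted p = 0.986). FOS differed between the resting arrays, at 33839 in M and 3654 in T.

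NF-kB pathway genes and genes of cytokine signalling also moved in both directions. IER3 (27.6-fold), BCL2A1 (7.32-fold), TRAF1 (4.36-fold) and ICAM1 rose, while TNFAIP3, a feedback inhibitor of NF-kB (3.52-fold), BIRC2 and NFKBIZ fell, which made 4 higher (3 to 7 over the alternatives) and 3 lower of 18 tested, or 5 and 3 adjusted over the list alone (median log2 0.52, limma camera adjusted p = 0.113, and adjusted p = 0.563 with an estimated correlation). Of 34 cytokine signalling genes, 10 rose (5 to 13 over the alternatives) and 7 fell (3 to 9), or 12 and 9 adjusted over the list alone, with a median log2 fold change of -0.03 and a mean of 0.19 (limma camera adjusted p = 0.636). CISH, a feedback inhibitor of cytokine receptors (17.2-fold), IL12RB2 (11.2-fold) and DUSP4 (7.63-fold) rose, and DUSP1 fell 24.0-fold. The NF-kB list passed camera without resting T (adjusted p = 0.024).

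Genes of quiescence and lymphoid homing fell. Of 24 tested, 18 fell and 0 rose, with a median log2 fold change of -2.49 (limma camera adjusted p = 3.52e-15, and adjusted p = 0.338 with an estimated correlation), and adjusted over the list alone 22 fell and 1 rose. Besides KLF2, TSC22D3 and PIK3IP1, the Krüppel-like factor gene KLF3 fell 10.5-fold (log2 -3.40 ± 0.36). IL7R, the interleukin-7 receptor (-3.09 ± 0.24), CDKN1B, an inhibitor of cyclin-dependent kinases (-2.75 ± 0.27), S1PR1, a receptor for egress from lymph nodes (-2.29 ± 0.30), and the homing receptor gene CCR7 (-1.72 ± 0.27) fell too. All but 1 of the GIMAP genes, small GTPases of lymphocytes, fell as well, 6 of 7 tested both over all probe sets and adjusted over the list alone (median log2 -2.34, limma camera adjusted p = 9.41e-06, and adjusted p = 0.338 with an estimated correlation). The examples GIMAP1, GIMAP2, GIMAP4 and GIMAP7 fell 8.03-fold, 7.33-fold, 6.52-fold and 5.08-fold, and GIMAP5 did not pass (log2 -0.55 ± 0.76).

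The T-cell receptor complex and its signalling genes were lower in 13 of 27 tested genes (4 to 15 over the alternatives) and higher in 0, or lower in 15 and higher in 1 adjusted over the list alone (median log2 -1.02, limma camera adjusted p = 9.71e-06, and adjusted p = 0.344 with an estimated correlation). CD4 itself fell 3.28-fold (log2 -1.71 ± 0.37), from 8129 ± 971.4 to 2559 ± 1112 (SD, n = 2 per group, limma adjusted p = 0.00643). The T-cell receptor chain genes CD3E and CD247 fell 2.03-fold and 3.71-fold, the kinase gene TXK 9.98-fold and the adaptor gene TRAT1 5.17-fold. LCK (log2 -0.44 ± 0.30) and LAT (0.21 ± 0.32) did not pass.

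Of 26 helper lineage and regulatory genes tested, 9 were lower, 2 were higher and 15 did not pass the threshold, or 11 lower and 2 higher adjusted over the list alone (median log2 -0.60, limma camera adjusted p = 0.00241, and adjusted p = 0.344 with an estimated correlation). CXCR4, a chemokine receptor, fell 26.5-fold (log2 -4.73 ± 0.28), KLRB1 24.2-fold, GZMA, a cytotoxic protease, 18.2-fold and CCR10 8.59-fold. TBX21, the lineage factor of type 1 helper cells (log2 2.78 ± 0.38), and GZMB (3.08 ± 0.88) were the 2 that rose. FOXP3 (-0.16 ± 0.48) and GATA3 (-0.67 ± 0.26) did not pass. The survival and apoptosis list showed 1 rise, BCL2L1 (17.2-fold), and 5 falls, among them CASP8 (6.47-fold), MCL1 (3.33-fold) and GADD45B (3.25-fold), of 25 tested (3 to 5 falls over the alternatives), with the same counts adjusted over the list alone. Its median log2 fold change was 0.15 and its mean -0.10 (limma camera adjusted p = 0.636).

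Interferon-stimulated genes were lower in 15 of 31 tested genes (5 without activated M, up to 16 in other alternatives) and higher in 3, or 16 and 3 adjusted over the list alone (median log2 -1.21, limma camera adjusted p = 5.21e-04, and adjusted p = 0.393 with an estimated correlation). ISG20 fell 9.61-fold (log2 -3.26 ± 0.37), SAMD9 8.39-fold, IFIT1 6.21-fold and MX2 5.39-fold. The 3 that rose were the guanylate-binding protein genes GBP5 (log2 2.33 ± 0.36), GBP1 (2.05 ± 0.41) and GBP2 (1.06 ± 0.32).

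Genes of the G1/S transition and DNA replication rose, while mitotic genes showed few changes. Of 34 G1/S genes tested, 24 rose (12 without activated M, up to 26 in other alternatives) and 0 fell, with a median log2 fold change of 1.88 (limma camera adjusted p = 1.73e-12, and adjusted p = 0.338 with an estimated correlation), or 26 and 0 adjusted over the list alone. MCM2, a subunit of the replicative helicase, rose 16.1-fold (log2 4.01 ± 0.34), UHRF1 13.7-fold, GINS2 13.2-fold and CDC45 11.5-fold. Of 22 G2/M genes tested, 4 rose (2 to 7 over the alternatives) and 0 fell, or 7 and 2 adjusted over the list alone, with a median log2 fold change of 0.04 (limma camera adjusted p = 0.586). These 4 were CDC20 (5.85-fold), CCNB1 (5.20-fold), AURKA (4.47-fold) and UBE2C (2.41-fold), whereas the proliferation marker MKI67 (log2 0.04 ± 0.48) and TOP2A (-0.80 ± 0.54) did not pass. The difference between the lists was not tested.

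**Figure D2:**
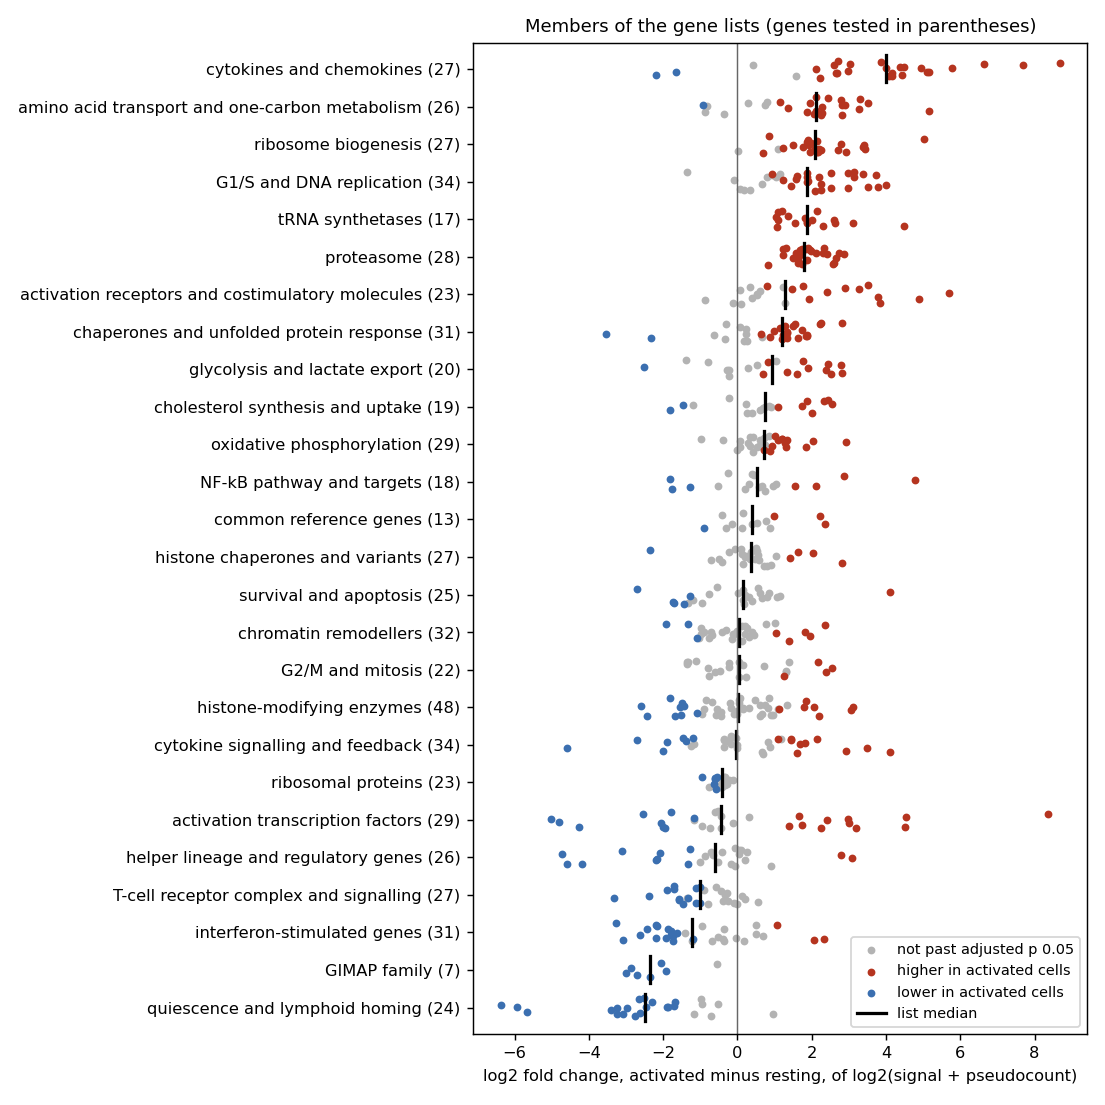
Log2 fold change (activated minus resting) of each tested member of the 26 gene lists, 1 point per gene, with the number of genes tested in parentheses and a black bar at each list's median. Red points are higher and blue points lower in activated cells at a limma adjusted p under 0.05, and grey points did not pass; medians run from -2.49 for quiescence and lymphoid homing to 3.99 for cytokines and chemokines.

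Energy metabolism genes rose in part. Of 20 genes of glycolysis and lactate export, 11 rose and 1 fell, or 13 and 2 adjusted over the list alone (median log2 0.93, limma camera adjusted p = 1.07e-04, and adjusted p = 0.344 with an estimated correlation). HK2, a hexokinase, rose 7.01-fold (log2 2.81 ± 0.34), PKM 6.90-fold and TPI1 5.71-fold, while the glucose transporter gene SLC2A3 fell 5.73-fold and SLC2A1 did not pass (log2 -0.28 ± 0.47). Of 29 oxidative phosphorylation genes, 13 rose (3 without activated M or without the variance trend, 5 without activated T, up to 16 in other alternatives) and 0 fell, or 16 and 0 adjusted over the list alone (median log2 0.73, limma camera adjusted p = 2.82e-06, and adjusted p = 0.344 with an estimated correlation). ATP5MC1, an ATP synthase subunit (7.64-fold), CYC1 (4.06-fold), NDUFB3 (3.63-fold) and COX5A (2.53-fold) had the largest rises. Of 19 cholesterol genes, 7 rose and 2 fell, with the same counts adjusted over the list alone (median log2 0.74, limma camera adjusted p = 0.00744, and adjusted p = 0.393 with an estimated correlation). SQLE (5.85-fold), HMGCS1 (5.45-fold), MSMO1 (5.05-fold) and NSDHL (4.04-fold) rose, and SC5D (log2 -1.81 ± 0.31) and IDI1 (-1.47 ± 0.46) fell.

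Amino acid and one-carbon metabolism genes and tRNA synthetases rose. Of 26 genes of amino acid transport and one-carbon metabolism, 19 rose and 1, SLC7A6, fell, or 19 and 2 adjusted over the list alone (median log2 2.12, limma camera adjusted p = 3.67e-10, and adjusted p = 0.338 with an estimated correlation). After PSAT1, the largest rises were those of SRM, an enzyme of polyamine synthesis (11.5-fold), the glutamine transporter gene SLC1A5 (9.76-fold) and PAICS, an enzyme of purine synthesis (9.74-fold). All 17 tRNA synthetase genes tested rose, over all probe sets and adjusted over the list alone, but 8 passed without activated M, 12 without activated T and 10 without the variance trend (median log2 1.86, limma camera adjusted p = 1.2e-11, and adjusted p = 0.338 with an estimated correlation). WARS1 rose 22.3-fold (log2 4.48 ± 0.30), FARSA 8.67-fold, RARS1 6.14-fold and IARS1 6.07-fold.

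Ribosome assembly factors rose and ribosomal protein genes were slightly lower. Of 27 ribosome biogenesis genes, 25 rose and 0 fell, or 26 and 0 adjusted over the list alone (median log2 2.09, limma camera adjusted p = 2.03e-16, and adjusted p = 0.338 with an estimated correlation), with BYSL, RRP9 (10.9-fold), NOP16 (10.6-fold) and WDR12 (10.4-fold) as the largest. NPM1 (log2 0.02 ± 0.18) did not pass. Of 23 ribosomal protein genes, 6 fell (0 without activated M or without activated T, 12 without resting T) and 0 rose, or 9 and 0 adjusted over the list alone (median log2 -0.42, limma camera adjusted p = 1.38e-05, and adjusted p = 0.493 with an estimated correlation). RPL22 fell 1.92-fold (log2 -0.94 ± 0.26), RPL30 1.56-fold, RPL11 1.53-fold and RPS27 1.52-fold. Only 1 of 5 tested probe sets of RPL22 and 1 of 2 of RPS27 passed the threshold. The list's median was -0.16 with quantile normalization and with arrays centred on their medians, and its calls then numbered 1 and 0. Its calls also numbered 0 without the variance trend and with no filter on dim probe sets. Under both scalings it passed camera as lower at the preset correlation of 0.01 (limma camera adjusted p = 0.00704 and 0.00566). The correlation estimated for the list was 0.734, so these p-values treat its genes as nearly independent although they varied together. These genes were among the brightest on the arrays, and RPL30 had signals of 183447 ± 21531 in resting and 117076 ± 222.7 in activated cells (SD, n = 2 per group).

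Members of the proteasome list rose in 28 of 28 tested, over all probe sets and adjusted over the list alone (median rise 3.47-fold, limma camera adjusted p = 1.31e-19, and adjusted p = 0.338 with an estimated correlation). The list did not hold every related symbol. Among all tested genes with PSMB symbols 9 of 11 rose and 1 fell, and among those with PSMD symbols 9 of 13 rose and 1 fell. PSMB5 rose 7.30-fold (log2 2.87 ± 0.35), PSMD3 6.69-fold, PSMD1 6.26-fold and PSMA5 6.05-fold. Of 31 chaperone and unfolded protein response genes, 20 rose (9 without activated M or without the variance trend, up to 22 in other alternatives) and 2 fell, or 21 and 2 adjusted over the list alone (median log2 1.21, limma camera adjusted p = 1.35e-06, and adjusted p = 0.344 with an estimated correlation). Subunits of the chaperonin that folds actin and tubulin rose, with CCT5 7.10-fold and CCT7 4.79-fold higher, while the stress-induced genes DNAJB1 (11.7-fold) and DDIT3 (log2 -2.32 ± 0.48) fell. HSPA5, the main chaperone of the endoplasmic reticulum, did not pass (log2 0.08 ± 0.21).

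Genes of chromatin, the subject of the series, changed in both directions. Of 32 chromatin remodeller genes, 5 rose (1 to 7 over the alternatives) and 3 fell, with the same counts adjusted over the list alone (median log2 0.06, limma camera adjusted p = 0.986). RUVBL2 (5.13-fold, log2 2.36 ± 0.29) and RUVBL1 (3.54-fold), ATPases of several remodelling complexes, ACTL6A (3.84-fold), HELLS and SMARCB1 rose, while CHD2 (3.83-fold), CHD1 and SMARCA2 fell. The ATPase gene SMARCA4 (log2 0.78 ± 0.35) did not pass. Of 27 histone chaperone and variant genes, 4 rose (2 to 7 over the alternatives) and 1 fell, with the same counts adjusted over the list alone (median log2 0.37, limma camera adjusted p = 0.0362, and adjusted p = 0.344 with an estimated correlation). NPM3 rose 7.08-fold, H2AX 3.07-fold and both subunits of the histone chaperone FACT, SSRP1 (4.13-fold) and SUPT16H (log2 1.41 ± 0.31), rose, while HMGB2 fell 5.07-fold. The list did not pass with quantile normalization (adjusted p = 0.0885) or without activated M (adjusted p = 0.192).

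Histone-modifying enzymes went both ways, with 7 of 48 tested genes higher (4 to 12 over the alternatives) and 9 lower (4 to 10), or 8 and 9 adjusted over the list alone (median log2 0.02, limma camera adjusted p = 0.986). The arginine methyltransferase genes PRMT5 and PRMT1 rose 8.70-fold (log2 3.12 ± 0.32) and 8.40-fold (3.07 ± 0.27). EZH2 (2.05 ± 0.40) and EED (1.85 ± 0.30), subunits of Polycomb repressive complex 2, rose as well. The histone demethylase gene KDM3A fell 6.10-fold, the deacetylase gene HDAC5 5.40-fold, and EZH1, the paralogue of EZH2, also fell (log2 -1.53 ± 0.42). DNMT1 (0.60 ± 0.31) and EP300 (-0.91 ± 0.41) did not pass.

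Several genes often used as references changed. Of 13 tested, TUBB (5.15-fold), ALAS1 (4.68-fold) and HPRT1 (1.98-fold) rose and YWHAZ fell 1.86-fold, with the same counts adjusted over the list alone (median log2 0.39, limma camera adjusted p = 0.115, and adjusted p = 0.383 with an estimated correlation). ACTB (log2 0.13 ± 0.20) and B2M (-0.31 ± 0.17) did not pass. YWHAZ did not pass with arrays centred on their medians.

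Markers of other cell types were measured beside these groups. Monocyte markers were lower in activated cells, 2 of 9 tested genes passing the threshold and 6 adjusted over the list alone (median log2 -2.16, limma camera adjusted p = 0.01, and adjusted p = 0.556 with an estimated correlation). LYZ, a lysozyme of myeloid cells, fell 21.3-fold (log2 -4.41 ± 0.77), with signals of 3942 in resting M, 26724 in resting T, 190.7 in activated M and 925.1 in activated T, and MNDA fell 4.58-fold. Without resting T the list's median was -1.02 and it did not pass (adjusted p = 0.239). These markers moved in the same direction as the quiescence, T-cell receptor, helper lineage, GIMAP and interferon-stimulated genes, each of which passed camera without resting T.

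Natural killer cell markers were lower in 2 of 6 tested genes, or 3 adjusted over the list alone, KLRF1 (4.86-fold) and FGFBP2 (4.10-fold), with a median log2 fold change of -1.50 (limma camera adjusted p = 0.0359, and adjusted p = 0.344 with an estimated correlation). The list did not pass without resting T (median -0.94, adjusted p = 0.177) or without activated M (median -0.79, adjusted p = 0.0584). Of 3 CD8 T cell markers, GZMK fell (log2 -4.46 ± 0.43), the 1 call both over all probe sets and adjusted over the list alone (list median -1.46, limma camera adjusted p = 0.0362, and adjusted p = 0.393 with an estimated correlation), and without activated M the list did not pass (median -0.22, adjusted p = 0.0864), its median being -2.88 without activated T. CD8B had signals of 471.5 and 396.4 in the resting arrays and 120.6 and 364.1 in the activated arrays. The list result does not cover CD8A, which was at or above the array median in resting T only and was not tested. Its signals were 54.58 in resting M, 497.5 in resting T, 28.4 in activated M and 27.59 in activated T. GZMK had signals of 12110 in resting M and 5663 in resting T. No member of the B cell, platelet, erythroid, neutrophil or dendritic cell lists passed the threshold, and the camera adjusted p was 0.248 for the B cell list and 0.822 for the platelet list, the other 3 having under 3 tested genes. Adjusted over the list alone, 2 B cell markers, 1 neutrophil marker and 1 dendritic cell marker were lower. The platelet result does not cover PPBP and PF4, which were at or above the array median in resting T only and were not tested. Their signals were 2226 and 864.7 in resting T against 27.45 and 116.8 in resting M. Every platelet marker measured was higher in resting T than in resting M. The strongest members were MS4A1 (log2 -1.82 ± 0.69) and CR2 (-1.65 ± 0.64) for B cells, TUBB1 (-0.98 ± 0.63) and ITGA2B (0.37 ± 0.95) for platelets, HBD (0.82 ± 0.69) and HBB (0.75 ± 0.81) for erythroid cells, FCGR3B (-1.86 ± 0.71) for neutrophils and FCER1A (-1.72 ± 0.61) for dendritic cells.

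With the preset correlation, 12 of the 31 lists tested passed camera as higher and 9 as lower. With an estimated correlation 0 lists passed after adjustment and 4 had an unadjusted p under 0.05, and 16 lists passed fry. Of 6127 genes with at least 2 tested probe sets, 2087 had at least 1 called probe set and 11 had probe sets called in both directions, among them CFLAR, CREM and the splicing factor genes SRSF3 and HNRNPD.

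**Figure D3:**
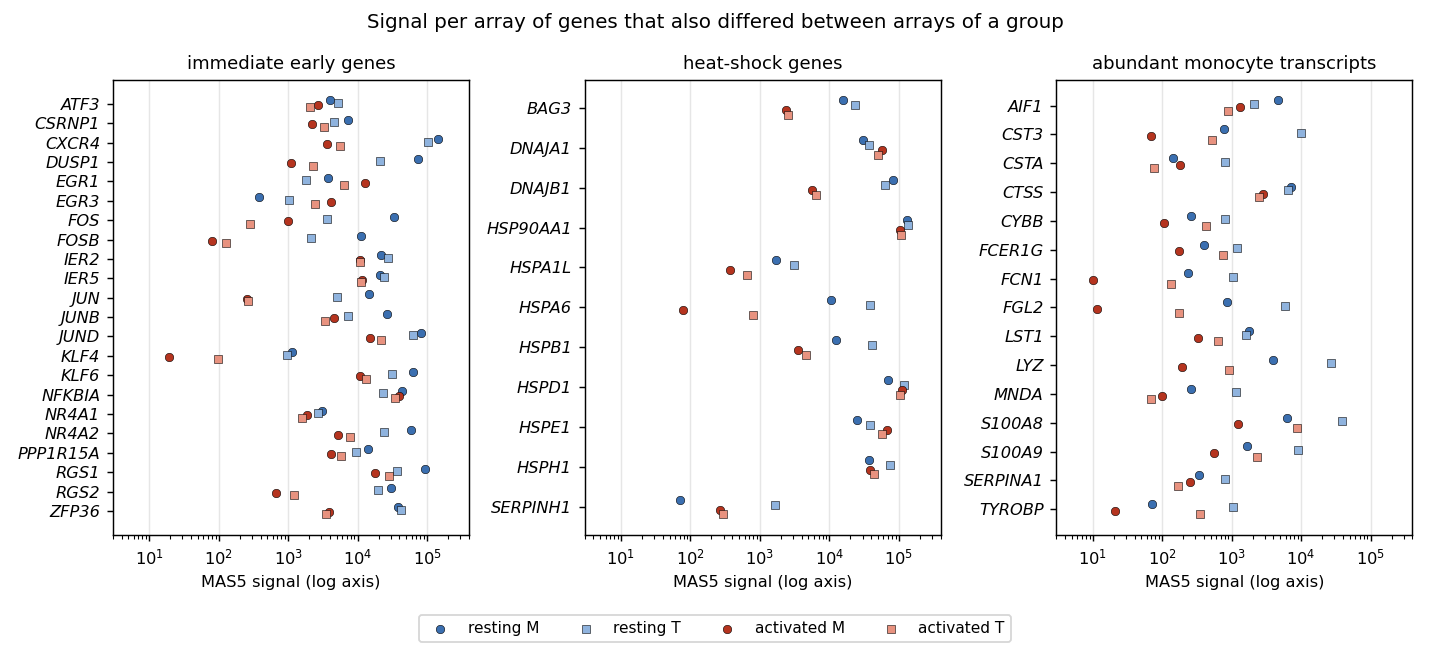
Signal in each of the 4 arrays of immediate early genes, heat-shock genes and abundant monocyte transcripts, 1 point per array, on a log axis of MAS5 signal, with circles for M, squares for T, blue for resting and red for activated. Of 22 immediate early genes 17 were higher in resting M than in resting T, and of 15 monocyte transcripts 12 were higher in resting T than in resting M.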

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

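Every alternative was fixed before the data were examined. Of the 122 named genes past the threshold, all kept their direction under each alternative in which they were tested, 103 kept their call under all but those that left out an array, and 99 under all of them. The filter at the 75th percentile tested 116 of the 130 named genes and 27 of the 31 lists. Calls that ended under at least 3 alternatives were those of AURKA, UBE2C, RPL22, RPL30, RPL11, RPS27, H2AX, IFIT1, HPRT1, YWHAZ, MNDA, KLRF1, FGFBP2 and CD3E. Changes to the pseudocount, the scaling, the filter and the gene value left 2298 to 3070 genes past the threshold, against 2934, and 17 to 21 lists past camera, against 21. Without the variance trend 3160 probe sets (1281 higher, 1879 lower) and 1493 genes (775 higher, 718 lower) passed, 1411 of the genes being shared with the 2934; the cause was not tested. With an estimated correlation 0 lists passed camera, 4 at an unadjusted p under 0.05, and 16 passed fry; in simulated data the estimated correlation called none of 4 shifted lists. Leaving out 1 array at a time, with the lone array assumed to vary like the other group, gave 2319 to 6802 probe sets (843 to 3240 higher, 1476 to 3562 lower) and 1134 to 3415 genes (554 to 1892 higher, 580 to 1523 lower), and the lowest counts came without activated M.

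The histone chaperone list did not pass with quantile normalization, the 75th percentile filter, the mean of probe sets, or without resting M or activated M. The monocyte list did not pass without resting T or with the 75th percentile filter, the natural killer cell list without resting T, without activated M or with no filter, and the CD8 list without activated M. fry did not call the ribosomal protein, interferon-stimulated, T-cell receptor, helper lineage, monocyte and CD8 lists. The NF-kB list passed with no filter and without resting T, and the common reference list passed fry.

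Directions turned only in results that passed no threshold in either setting, and the cause was not tested. For lists the direction is that of the test and the value the median log2 fold change. Activation transcription factors had -0.46 with no pseudocount and with a floor, -0.51 with quantile normalization, -0.20 with centred arrays and -0.45 with the 75th percentile filter. Cytokine signalling had -0.16 with quantile normalization. Chromatin remodellers had 0.02 with quantile normalization and -0.01 with the 75th percentile filter. Histone-modifying enzymes had 0.02 with a floor, with the 75th percentile filter and with fry, and 0.08 with quantile normalization. HBB had -0.13 as the mean of its probe sets. Leaving out arrays gave ranges of -0.51 to -0.31 for activation transcription factors, -0.08 to 0.05 for chromatin remodellers, -0.15 to 0.19 for histone-modifying enzymes, -1.30 to 1.23 for platelet markers, -1.20 to 1.94 for ITGA2B and -0.19 to 1.69 for HBB.

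With the letter as a replicate block, 7495 probe sets (3182 higher, 4313 lower) and 3608 genes (1879 higher, 1729 lower) passed, and all 2934 gene calls made without the block were among them. Nothing states that the letters mark paired samples. The M minus T differences of the resting and activated arrays correlated at r = 0.095 across probe sets, with XIST and Y-linked genes left out. A low correlation over all these probe sets does not exclude pairing. Of the 54675 probe sets, 25643 were too dim to be tested, and changes among them were not examined.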

Other observations

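Many genes of the mitochondrial ribosome rose with activation. These families, taken from shared gene symbol stems, were chosen after the data were seen. Genes of the large mitochondrial ribosomal subunit rose in 33 of 49 tested, with 0 falls (median log2 1.28, limma camera adjusted p = 4.08e-12), and those of the small subunit in 19 of 27, with 0 falls (median 1.27, adjusted p = 1.77e-10), and neither passed with an estimated correlation (adjusted p = 0.783 for both). MRPS17 rose 6.92-fold (log2 2.79 ± 0.32, SE) and MRPL12 6.88-fold (2.78 ± 0.36). The TIMM genes, which import proteins into mitochondria, rose in 8 of 14, with TIMM13 7.39-fold higher. RNA polymerase subunits rose in 16 of 32, POLR1G of RNA polymerase I by 9.86-fold. The UTP genes of early ribosome assembly rose in 8 of 10, the EXOSC genes of the RNA exosome in 7 of 10, EXOSC4 by 8.48-fold, the LSM genes of RNA processing in 9 of 13 and the NUP genes of the nuclear pore in 10 of 23, all with 0 falls. Krüppel-like factors fell in 8 of 14 with 0 rises (median log2 -1.95, adjusted p = 1.21e-04), KLF4 by 10.8-fold, and the ZBTB zinc finger genes fell in 7 of 38 with 1 rise (median -0.62, adjusted p = 0.0269), ZBTB18 by 10.1-fold, and neither passed with an estimated correlation (adjusted p = 0.783 for both). The DHX helicase genes, with 5 rises and 1 fall of 16, passed camera (adjusted p = 0.0415) and did so with centred arrays (adjusted p = 0.039), but not with quantile normalization (adjusted p = 0.0641) or an estimated correlation (adjusted p = 0.783). Families of RNA synthesis and processing that did not pass camera (adjusted p = 0.0949 to 0.991) included GTF with 6 rises of 26, INTS with 4 of 17, PRPF with 2 of 11 and TAF with 1 of 23, each with 0 falls, DDX with 8 rises and 4 falls of 32, RBM with 5 and 2 of 34 and MED with 1 and 3 of 26. Of the 132 families tested, 24 passed camera and 0 with an estimated correlation. Among the 24, the DHX, ALG, EIF, EMC, GPR, NDUFA, NDUFB and RPL families did not pass with quantile normalization (limma camera adjusted p = 0.0641 to 0.15). The 11 families described above that passed camera kept their direction with quantile normalization and with centred arrays.

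Of the tests that follow, those of array scaling, of a signal ceiling and both on monocyte transcripts were chosen after the result was seen, as was the use of the activated arrays to judge handling. No biological explanation was tested.

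Ribosomal protein genes were slightly lower in activated cells while ribosome assembly genes rose. Array scaling cannot be told apart as the cause, since the list's median moved from -0.42 to -0.16 with quantile normalization and with centred arrays. Its calls then fell from 6 to 1 and 0. Its mean difference was -0.46 ± 0.14 (SE over arrays) with the deposited scaling, -0.18 ± 0.08 with quantile normalization and -0.20 ± 0.15 with centred arrays. The upper 95% limits were 0.16, 0.15 and 0.45, so a difference of 0 was not excluded over arrays under any scaling. At the preset correlation the list kept its camera call with quantile normalization and with centred arrays (adjusted p = 0.00704 and 0.00566). The 40 genes with RPL symbols, a family drawn up after the data were seen, did not (adjusted p = 0.0641 and 0.0668). The list lay at percentile 0.66 among lists matched on brightness, but those had a mean log2 signal of 15.2 against 16.33, so the bound set beforehand did not test genes as bright and a fall of all bright probe sets cannot be told apart. A signal ceiling that differs between arrays had the values it needs, since the 6 other genes as bright as the median ribosomal protein gene had a median log2 fold change of -0.29, with 5 negative and 0 past the threshold. A wider set, added because 6 genes were few, held 13 genes with a median of -0.31. Array scaling or a fall of all bright probe sets could give such values too, so they do not single out a ceiling.

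Immediate early genes, listed like the heat-shock genes after falls of several members were seen, were lower in activated cells in 17 of 22 tested and higher in 2 (median log2 -1.83), and heat-shock genes lower in 5 of 11 and higher in 1 (median -0.45). The resting arrays differed by a median absolute log2 of 0.78 in the immediate early and 0.75 in the heat-shock genes, at percentiles 99.99 and 99.87 among lists matched on brightness, with 17 of 22 immediate early but 1 of 11 heat-shock genes higher in resting M than in resting T. This does not show handling of the resting cells as the reason for the falls, because the activated arrays also differed in the immediate early genes, at percentile 99.97, though not in the heat-shock genes, at percentile 39.26. In both resting arrays 19 of 22 immediate early and 6 of 11 heat-shock genes were higher than in both activated arrays. Since the lists were drawn up after falls of members were seen, these counts do not bear on handling. Handling that both resting preparations shared was not tested. The arrays included 0 labelled as unstimulated cultures of 18 hours, and the sources used here do not say how long the resting cells were in culture. Unless the resting cells were cultured as long, time in culture and stimulation cannot be told apart as reasons for these falls. The same limit holds for any other difference between the groups.

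Abundant monocyte transcripts were lower in activated cells in 7 of 15 tested and higher in 0 (median log2 -1.74), within M by -1.52 and within T by -1.95. They were higher in T than in M in 12 of 15 in the resting arrays and 10 of 15 (66.7%) in the activated arrays, by medians of 1.97 and 1.62 (SD over genes 1.34 and 1.25), at percentile 100 among lists matched on brightness in both. More monocyte RNA in the T preparations cannot be told apart from other differences between M and T by this test. Its genes were listed after the pattern was seen, and the share lay between the bounds of 90% and 60% set for it. The monocyte markers fixed beforehand were not put to the test. All of those measured were higher in resting T than in resting M, and all but MNDA were higher in activated T than in activated M. Some were near background, such as CD14 at 21.22 in resting M and 29.88 in resting T. Monocyte RNA in resting T alone as the main cause of the genes lower in activated cells was argued against by the 1165 of 1376 such genes (84.7%) that kept the call without that array. That fit had 1 resting array, assumed to vary like the activated arrays, and called more genes lower in all, so the share may be too high. It does not address monocyte RNA in resting M, in which LYZ had a signal of 3942 against 190.7 in activated M.

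Spike-in control probe sets were dimmer in the activated arrays, 8 of 9 probe sets being lower in both activated arrays than in both resting arrays. Their median log2 signal relative to resting M was -0.258 in resting T, -0.359 in activated M and -0.662 in activated T.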
